A study of Mus musculus with 10 samples.

How the data were processed

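RNA was sequenced from 10 libraries of sorted mouse bone marrow cells on a C57BL/6 background. The groups were taken from the sample labels: pro-B control (2 libraries), pro-B Mta2 KO (2), small pre-B control (3) and small pre-B Mta2 KO (3). The pre-B, OcaB KO and double KO samples that the series description names were not analysed here. The labels do not state which animals, litters, sexes, sequencing runs or days the libraries came from, so replicates are libraries and the p-values measure the spread between libraries. Cell type and sequencing batch cannot be told apart where every library of a cell type was handled together.

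The deposited files hold raw read counts per gene symbol, 1 library per file, with no normalization. Per the file headers the authors counted reads over exons with featureCounts 1.4.3-p1 and an mm10 annotation, with no strand option, while the kit named in the labels keeps the strand. Counts of genes that overlap on opposite strands are therefore less certain. The submitters' processing notes name CASAVA 1.82, STAR and genome mm9, whereas the exon coordinates in the files are mm10, and positions are given here in mm10. The file header of small pre-B control 3 carries the number 919 while its title carries 931.

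Total counts ranged from 17805507 to 52127004 per library, and a floor of 3 counts corresponded to 0.054 to 0.173 CPM. Counting intervals of ratios are exact binomial intervals at 95%, and a fold against a group with 0 counts was computed against a floor of 3 counts over the group. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

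Differential expression was tested with edgeR 4.0.16 (R 4.3.3). Genes were filtered with filterByExpr by group (minimum count 10, minimum total count 15), which left 14161 of 23420 genes. Libraries were scaled by trimmed mean of M values (TMM), and 1 model with a mean for each of the 4 groups was fitted to all 10 libraries with robust quasi-likelihood dispersions. The quasi-likelihood F-test was used for Mta2 KO against control in pro-B cells, the same in small pre-B cells, the difference of these effects, and small pre-B against pro-B controls. P-values were adjusted by Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05. Levels are TMM-scaled CPM with SD over libraries, and fitted log2 fold changes use a prior count of 0.125.

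The choices that follow were made before the data were examined. The 20 gene lists covered the NuRD complex, the surrogate light chain and pre-B cell receptor, V(D)J recombination, B lineage transcription factors, the interleukin-7 receptor pathway, G2 and M phase, S phase, immature and mature B cells, immunoglobulin genes, p53 targets, immediate early genes, the interferon response, sex-linked genes and markers of T, natural killer, myeloid, plasmacytoid dendritic, erythroid, stem and plasma cells. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset correlation of 0.01, a two-sided test and Benjamini-Hochberg adjustment over 19 lists per comparison, and again with the correlation estimated per list. The immunoglobulin list had 0 of 8 members among the tested genes and was not analysed here. The genes named are Mta2, a fixed set of 8 genes of early B cells, the 10 genes with the largest change in each direction (5 for the difference and for the stages) among those past the threshold with a mean of at least 2 CPM and with every KO library beyond every control, leaving out predicted and small RNA genes, and up to 4 members of each list with the smallest p. Where fewer than 3 genes passed in a direction, the 5 with the smallest p were named as not passing. The results of some single genes that this rule picks are not reported here. Histone genes, and the genes beside Cd3e, were chosen after their values were seen.

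Correlations of log2 fold changes are across genes. The relation between the KO effect and the stage difference, which share the small pre-B controls, was set beside 20 simulated data sets with no KO effect and, chosen after the results were seen, beside fits with the small pre-B controls divided into separate sets for the KO effect and the stage difference, where a lone control was assumed to vary like the other groups. The overlap of calls was tested with Fisher's exact test, two-sided.

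The alternatives chosen before the data were examined were DESeq2 size factors and upper-quartile scaling in edgeR, the DESeq2 1.42.0 Wald test, limma-voom, no count filter, a filter of 1 CPM in every library of a group, a fit of the compared groups alone, the number in the sample titles as a replicate block, an absolute log2 fold change of at least 1, and leaving out each library in turn. Where that left 1 library in a group, it was assumed to vary like the other groups. Chosen after seeing the data were the libraries with Y-linked RNA alone, Y-linked RNA as a covariate, leaving out Rn45s (the ribosomal RNA precursor, 0.281% to 2.73% of counts), removal of each library's GC trend (GC content was known for 99.2% of genes), the small pre-B libraries without control 3, and the header number as a block.

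The procedure was tested on simulated data of the same design with 13895 genes. Of genes changed 2-fold it called 47.8% in pro-B and 68.7% in small pre-B cells. The shares were 97% and 95.5% of genes changed 4-fold, and 5.97% and 13.4% of those changed 1.5-fold, with 7.41% and 6.35% of calls false. The changed genes had a mean of at least 5 CPM in both control groups, so these rates do not cover genes below that level. The simulation does not copy the larger spread of small pre-B control 3. Camera called a shifted set (adjusted p = 9.08e-26) and 0 of 100 random sets. The simulated genes varied independently of each other, so this does not test the preset correlation. In the data the estimated correlation reached 0.946, in the natural killer list. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Library pairs within a group were checked for duplicates, and none was one, with a chi-square per degree of freedom between 22.6 and 225.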

Results

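Transcript levels were measured by RNA sequencing in pro-B cells (B220+ IgM- CD43+) and in small pre-B cells (B220+ IgM- CD43-, gated for small size) sorted from the bone marrow of control mice and of mice with a Vav-driven knockout of Mta2. Mta2 is a subunit of the nucleosome remodelling and deacetylase (NuRD) complex, which removes acetyl groups from histones and moves nucleosomes. The 10 libraries formed 4 groups, with 2 control and 2 Mta2 KO libraries of pro-B cells and 3 control and 3 Mta2 KO libraries of small pre-B cells. Total counts were 48860391 and 52127004 in the pro-B controls 1 and 2, and 52011415 and 48988304 in the pro-B KO libraries 1 and 2. They were 18502193, 25291536 and 38392136 in the small pre-B controls 1 to 3. In the small pre-B KO libraries 1 to 3 they were 17805507, 25821264 and 22228725. A level of 3 counts corresponded to 0.054 to 0.173 CPM (counts per 1e6 counts of the library, scaled between libraries). Of the 23420 genes in the files, 14161 had enough counts to be tested.

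The first principal component held 74.1% of the variance and parted the cell types. The pro-B libraries lay at -131 to -108 and the small pre-B libraries at 52.9 to 115. Small pre-B control 3 stood apart on the second component (11.5% of the variance), at -91.9. The other small pre-B controls lay at -16.3 and 2.43, and the small pre-B KO libraries at 40.8 to 45.9. In that library the replication-dependent histone genes took 0.953% of all counts and the nuclear RNA Malat1 took 1.4%, against at most 0.0399% and 0.290% in the other 9 libraries. Sex-linked RNA also differed within the small pre-B KO group. Xist, the RNA of the inactive X chromosome, was at 2518 and 2942 CPM in small pre-B KO libraries 1 and 2, where the summed Y-linked genes were at 8.13 and 0.0790 CPM. The other 8 libraries had 224 to 674 CPM of Y-linked RNA and at most 31.4 CPM of Xist.

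Mta2 itself (chromosome 19, 8941920 to 8952300, mm10) had lower read counts in each KO library than in each control library of its cell type. In pro-B cells it was at 436 and 375 CPM in the controls and at 163 and 166 CPM in the KO libraries. The log2 fold change of -1.31 (SE 0.24) had an adjusted p of 0.212 and did not pass the edgeR quasi-likelihood test. Over 24 alternative fits its adjusted p lay between 0.000282 and 1. It was below 0.05 with DESeq2, with limma-voom, in the pro-B libraries fitted alone and without small pre-B control 2. In small pre-B cells it was at 438, 246 and 412 CPM in the controls and at 199, 179 and 198 CPM in the KO libraries. It fell by 0.93 on the log2 scale (SE 0.19, adjusted p = 0.042, edgeR quasi-likelihood). The counts are summed over all exons of the gene, so exons outside a deleted segment are counted too. The small pre-B call was lost in 16 of 25 alternative fits, with adjusted p between 0.000469 and 0.25 over all of them. Among fits that left out a single library, it was kept only without small pre-B control 2.

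**Figure D1:**
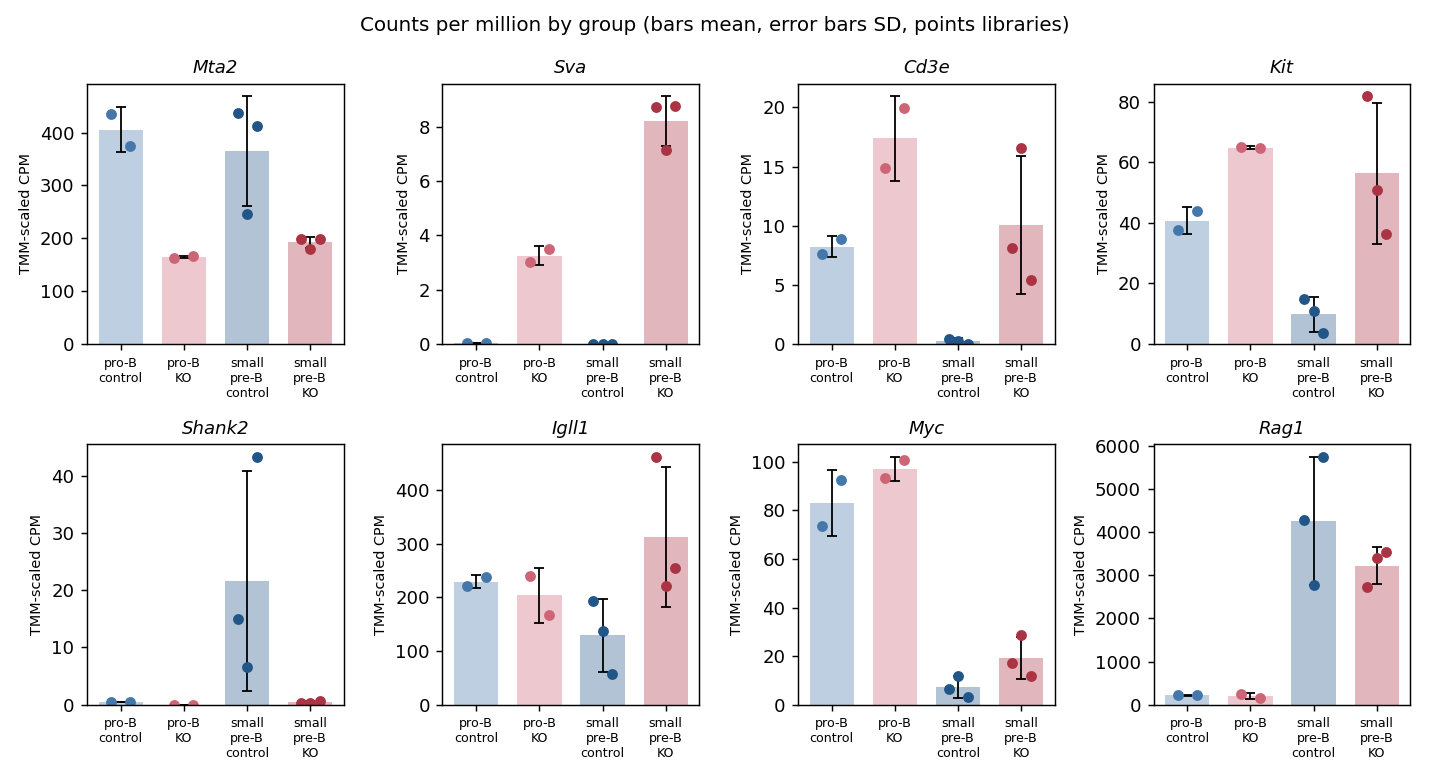
Normalised read counts (CPM, scaled by trimmed mean of M values) of 8 genes in the 4 groups. Bars are group means, error bars are SD and points are the libraries (2 per pro-B group, 3 per small pre-B group), and Mta2 lies lower in each KO library (163 to 199 CPM) than in each control (246 to 438 CPM).

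The comparison of Mta2 KO with control pro-B cells asked which transcripts depend on Mta2 at this early stage. The largest change was in Sva, a gene of the secreted seminal vesicle antigen (chromosome 6, 42038394 to 42042851), which rose from 0.0185 ± 0.000787 to 3.25 ± 0.345 CPM (SD, n = 2 per group). The KO libraries held 341 counts against 2 in the controls, a ratio of 175 with a 95% counting interval of 48 to 1448. Tjp1, a scaffold protein of tight junctions, rose from 0.720 ± 0.127 to 19.8 ± 2.33 CPM, and Klc3, a kinesin light chain, rose from 2.04 ± 0.241 to 9.87 ± 0.480 CPM. Olfml2b, an extracellular matrix protein, rose from 18.02 ± 0.647 to 63.0 ± 11.8 CPM, and the aldehyde dehydrogenase gene Aldh3b1 rose from 56.4 ± 0.714 to 118 ± 9.50 CPM. These 5 genes, 5 higher and 0 lower, were the ones with an adjusted p below 0.05 (edgeR quasi-likelihood). Their log2 fold changes were 7.20 for Sva, 4.77 for Tjp1, 2.27 for Klc3, 1.81 for Olfml2b and 1.07 for Aldh3b1. The adjusted p was 0.00851 for Sva, Klc3 and Olfml2b, 0.00885 for Tjp1 and 0.0404 for Aldh3b1. In each of them both KO libraries lay above both controls, as they did in either direction for 55.5% of all genes.

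No gene passed in the lower direction in this fit. The genes with the smallest p there, apart from Mta2, were Edaradd, Fam189a1, Cd209a and Igsf9. Edaradd, an adaptor of the ectodysplasin receptor, was at 22.7 ± 1.62 CPM in controls and 11.5 ± 2.12 CPM in KO (log2 fold change -0.98, adjusted p = 0.0785). The lectin receptor gene Cd209a was at 89.3 ± 7.71 and 25.5 ± 0.543 CPM (-1.81, adjusted p = 0.18). Fam189a1 was at -2.45 (adjusted p = 0.175) and Igsf9 at -1.48 (adjusted p = 0.18). The genes of B cell identity followed in each comparison did not pass either. Igll1 and Vpreb1, which encode the surrogate light chain, were at log2 fold changes of -0.17 and -0.04. Rag1 and Rag2, which encode the recombinase of antigen receptor genes, were at -0.08 and -0.20. The B lineage transcription factors Pax5 and Ikzf3 were at -0.56 and -0.18, Myc at 0.23 and Il7r, the interleukin-7 receptor, at -0.26. Their adjusted p ranged from 0.776 for Pax5 to 1 for the others.

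Of 19 gene lists that could be tested in pro-B cells, 1 was higher and 2 were lower as a group by camera with the preset correlation. The 16 measured markers of myeloid cells and granulocytes, a cell type other than the one sorted for, had a median log2 fold change of 0.96 (camera adjusted p = 0.00098). Of its members 0 passed over all genes and 0 adjusted over the list alone. The protease genes Ctsg and Prtn3 were at 31.6 ± 1.23 and 77.6 ± 8.07 CPM in controls and at 91.0 ± 53.5 and 234 ± 152 CPM in KO. The integrin gene Itgam was at 228 ± 13.1 and 359 ± 54.4 CPM. The 16 surrogate light chain and pre-B cell receptor genes had a median of -0.12 (camera adjusted p = 0.0482), with Blk at -0.55, Vpreb3 at -0.72 and Cd79b at -0.38. The 20 DNA replication and S phase genes had a median of -0.26 (camera adjusted p = 0.0435), with Pcna at -0.38. None of the members of either list passed, over all genes or adjusted over the list alone. With an estimated correlation none of the 3 lists was called (adjusted p = 0.899 with an estimated correlation for each). Adjusted over the list alone, 1 NuRD subunit was lower, Mta2, and 2 of the 8 plasmacytoid dendritic cell markers were lower. These were Klk1 (85.4 ± 21.7 CPM in controls and 7.01 ± 1.36 CPM in KO) and Cd209d (53.8 ± 3.0 and 5.06 ± 0.618 CPM). The median of those 8 markers was 0.02 while their mean was -0.77. The 14 T cell markers had a median of 0.32 (camera adjusted p = 0.262), with Cd3e at 1.08 and Lat at 1.20. The other lists had camera adjusted p from 0.195 to 0.986. The sign of the median, the mean and the test differed for the NuRD, mature B cell, immediate early, plasmacytoid dendritic cell and sex-linked lists.

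An unadjusted p below 0.05 was reached by 913 genes in pro-B cells. Fitting the 4 pro-B libraries alone gave 856 genes in place of 5, 168 of them lower, DESeq2 gave 181 with 42 lower and limma-voom 148 with 16 lower, while the replicate block of shared title numbers gave 0. The count was 0 without pro-B control 1, pro-B control 2 or pro-B KO 2, 14 without small pre-B control 2 and 25 without small pre-B control 3; the surrogate light chain and S phase calls were lost without pro-B control 1 (adjusted p = 0.241 and 0.433), pro-B KO 2 (0.448 and 0.144), small pre-B control 2 (0.0656 and 0.0523) or small pre-B control 3 (0.0931 for each), and the surrogate light chain call also without small pre-B KO 1 (0.0599) or KO 3 (0.0552).

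The same comparison in small pre-B cells, the later stage at which immunoglobulin light chain genes are rearranged, found 267 genes higher and 161 lower in Mta2 KO. Sva again had the largest change, from 0 counts in the 3 control libraries to 8.21 ± 0.916 CPM (SD, n = 3) in KO. It was at least 211-fold higher, with a floor of 3 counts over the group. Cd3e, a chain of the T cell receptor complex, rose from 0.252 ± 0.21 to 10.03 ± 5.81 CPM, and Kit, the stem cell factor receptor, rose from 9.80 ± 5.70 to 56.4 ± 23.3 CPM. Shank2, a postsynaptic scaffold, was among the genes that fell most and went from 21.6 ± 19.2 to 0.390 ± 0.187 CPM. Small pre-B control 3 had the highest value of Shank2, at 43.3 CPM, and KO libraries 1 and 2 were the ones with Xist RNA.

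Among the genes that rose most in small pre-B KO were also Tmem119 (log2 fold change 5.30), the adhesion molecule Mpzl2 (4.86) and Crhbp (4.80), which binds corticotropin-releasing hormone. The collagen chaperone Serpinh1 (4.21), Myl10 (4.09), the cyclophilin Ppic (3.91), Ddn (3.90) and the laminin chain Lama5 (3.86) rose as well. Their adjusted p were between 0.00596 for Tmem119 and 0.0414 for Crhbp (edgeR quasi-likelihood). Lama5 rose from 0.636 ± 0.310 to 9.59 ± 2.16 CPM and Tmem119 from 0.123 ± 0.0730 to 4.79 ± 2.3 CPM. Olfm4 was at least 5.48-fold lower, with 20 counts in controls and 0 in KO, and Cd209a had a ratio of 0.0239 (counting interval 0.000592 to 0.139), with 1 count in KO. The microtubule-associated proteins Map2 (-3.67) and Eml6 (-3.25), Zfp418 (-3.49), the transporter gene Abca6 (-3.02) and Egfl6 (-2.57) also fell. Egfl6 went from 34.99 ± 12.8 to 5.86 ± 1.51 CPM. Of the 428 genes that passed, 291 had an absolute log2 fold change of at least 1. In all 428 the 3 KO libraries lay beyond the 3 controls, which held for 25% of all genes, where chance gives 10% (3 against 3 libraries).

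T cell markers were the list with the strongest shift in small pre-B KO. Of 14 measured members 6 rose, 0 fell and 8 did not pass, and 11 were higher adjusted over the list alone. The list had a median log2 fold change of 1.97 (camera adjusted p = 1.34e-06). With an estimated correlation the list was not called (adjusted p = 0.863 with an estimated correlation). Cd3e, Cd3d, Cd3g and Cd247, which are chains of the T cell receptor complex, rose together with the adaptor Lat and the transcription factor Bcl11b. Cd3d rose from 0.854 ± 0.257 to 6.11 ± 3.95 CPM and Cd247 from 4.13 ± 1.04 to 12.6 ± 2.23 CPM. The coreceptor gene Cd4 had a log2 fold change of 0.11 (adjusted p = 0.959). The summed level of Cd4 and Cd8a was 0.808, 9.96 and 1.35 CPM in KO libraries 1 to 3 and 1.90, 3.46 and 0.824 CPM in controls 1 to 3. Cd3e was at 8.13 and 16.6 CPM in KO libraries 1 and 2, which had Xist RNA, and at 5.41 CPM in KO library 3, which had Y-linked RNA. It was lowest in control 3 (0.0284 CPM).

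Interferon response genes also shifted upward as a list. Of 15 members 1 passed over all genes and 10 were higher adjusted over the list alone, with a median of 1.13 (camera adjusted p = 2.54e-05). This call too was lost with an estimated correlation (adjusted p = 0.863 with an estimated correlation). Irf7, a transcription factor of the interferon response, rose from 8.68 ± 2.70 to 18.8 ± 3.11 CPM (adjusted p = 0.0482). Rtp4 (3.43 ± 1.17 and 11.4 ± 3.03 CPM), Oas1a (5.24 ± 1.54 and 11.9 ± 2.71 CPM) and Ifi44 (3.25 ± 2.46 and 12.1 ± 3.18 CPM) had adjusted p of 0.0507 to 0.0821. All 4 of these genes were lowest in control 3.

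Several lists of B cell differentiation and signalling were not called as lists in small pre-B KO but held members that passed over all genes or adjusted over the list alone. In the interleukin-7 receptor pathway 0 of 18 members passed over all genes and 6 were higher adjusted over the list alone (median 0.36, camera adjusted p = 0.137). Among these were the feedback inhibitors Socs2 (20.4 ± 17.9 CPM in controls and 92.1 ± 16.8 CPM in KO) and Socs3 (1.31 ± 0.229 and 4.96 ± 2.18 CPM). The cyclin gene Ccnd2 (23.7 ± 19 and 94.6 ± 43.7 CPM) and Myc (7.18 ± 4.45 and 19.4 ± 8.58 CPM) were others. Socs2, Socs3, Ccnd2 and Myc were lowest in control 3. Il7r itself had a log2 fold change of -0.16 (adjusted p = 0.482). Of 24 immature and mature B cell genes 2 rose, and 3 adjusted over the list alone (median 0.13, camera adjusted p = 0.907). The cytokine gene Ltb rose from 42.6 ± 8.29 to 90.5 ± 16.3 CPM. The chemokine receptor gene Cxcr5 was at 10.8 ± 10.8 and 57.5 ± 15 CPM (adjusted p = 0.0622). Of 14 p53 targets 1 rose, and 1 adjusted over the list alone (median 0.32, camera adjusted p = 0.137). This was the cell death gene Bbc3, which rose from 7.86 ± 2.31 to 16.9 ± 2.53 CPM. Of 8 plasma cell markers 1 rose, and 3 adjusted over the list alone (median 0.12, camera adjusted p = 0.374). Xbp1, a transcription factor of secretory cells, rose from 86.3 ± 1.19 to 125 ± 10.2 CPM.

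The lists at the centre of the pre-B stage had no member past the test over all genes in small pre-B KO. Of the 16 surrogate light chain and pre-B cell receptor genes 0 passed (0 adjusted over the list alone, median 0.07, camera adjusted p = 0.77). Igll1 was at 129 ± 68.4 CPM in controls and 312 ± 131 CPM in KO (adjusted p = 0.113), and Vpreb1 at 72.1 ± 48.6 and 176 ± 75.2 CPM (adjusted p = 0.171). Vpreb2 was at 4.45 ± 2.73 and 11.8 ± 4.62 CPM (adjusted p = 0.132) and the kinase gene Syk at 3660 ± 773 and 2670 ± 291 CPM (adjusted p = 0.13). Control 3 had the lowest Igll1, Vpreb1 and Vpreb2 and the highest Syk. Of the 13 V(D)J recombination genes 0 passed (0 adjusted over the list alone, median -0.15, camera adjusted p = 0.578), with Rag1 at -0.40, Rag2 at 0.24 and Prkdc at -0.87. Of the 23 B lineage transcription factors 0 passed (0 adjusted over the list alone, median 0.08, camera adjusted p = 0.409), with Pax5 at 0.13, Ikzf3 at 0.02, Id3 at 0.85, Erg at 1.17 and Pou2f2 at -0.52. The G2 and M phase list (0 of 20, median -0.15, camera adjusted p = 0.374, Mki67 at -0.53) and the S phase list (0 of 20, median 0.06, camera adjusted p = 0.907) had no member past the test, over all genes or adjusted over the list alone.

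Among the other lists in small pre-B KO, Mta2 was the 1 of 15 NuRD subunits to fall. Adjusted over the list alone Chd5 was lower too, and Mta3, Cdk2ap1 and Chd3 were higher (list median 0.23, camera adjusted p = 0.152). Mta3, a paralogue of Mta2, was at 83.1 ± 19.2 CPM in controls and 119 ± 1.72 CPM in KO (adjusted p = 0.0928). Kit was the 1 of 9 stem and progenitor markers to pass over all genes. Adjusted over the list alone Kit was higher and Meis1 lower (median 0.33, or 0.19 with members at 0 counts set at their bound, camera adjusted p = 0.941). Markers of natural killer cells (0 of 10, median 0.85, camera adjusted p = 0.108, Tbx21 at 1.62) and of myeloid cells (0 of 16, median 0.58, camera adjusted p = 0.137, Csf1r at 1.47) were not called. Nor were those of plasmacytoid dendritic cells (0 of 8, median -0.44, camera adjusted p = 0.94), of which 1, Bst2 at 0.98, was higher adjusted over the list alone. Erythroid markers (0 of 8, median 0.45, camera adjusted p = 0.743) and immediate early genes (0 of 16, median -0.36, camera adjusted p = 0.907) were not called either. In the natural killer, myeloid, erythroid and immediate early lists 0 members passed adjusted over the list alone. Of the 5 sex-linked genes 0 passed over all genes, and 1, Xist, was higher adjusted over the list alone (median -1.64, camera adjusted p = 0.173). The sign of the median, the mean and the test differed for the S phase, immediate early, plasma cell and sex-linked lists.

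In small pre-B cells 3495 genes had an unadjusted p below 0.05, and the count of 428 changed with the fit. The 6 small pre-B libraries fitted alone gave 0, and without control 3 they gave 5. The replicate block of shared title numbers gave 153. A block of the header numbers, which differ from the title for control 3, gave 0. DESeq2 gave 1821. Y-linked RNA as a covariate left 1, where the KO effect rests on small pre-B KO library 3 alone. Leaving out 1 library gave 1 gene without small pre-B control 1, 1667 without control 2, 280 without control 3, 4, 18 and 149 without small pre-B KO 1, 2 and 3, 10 without either pro-B control, and 15 and 14 without pro-B KO 1 and 2; of the 30 named genes that passed, 0 kept the call in every alternative.

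**Figure D2:**
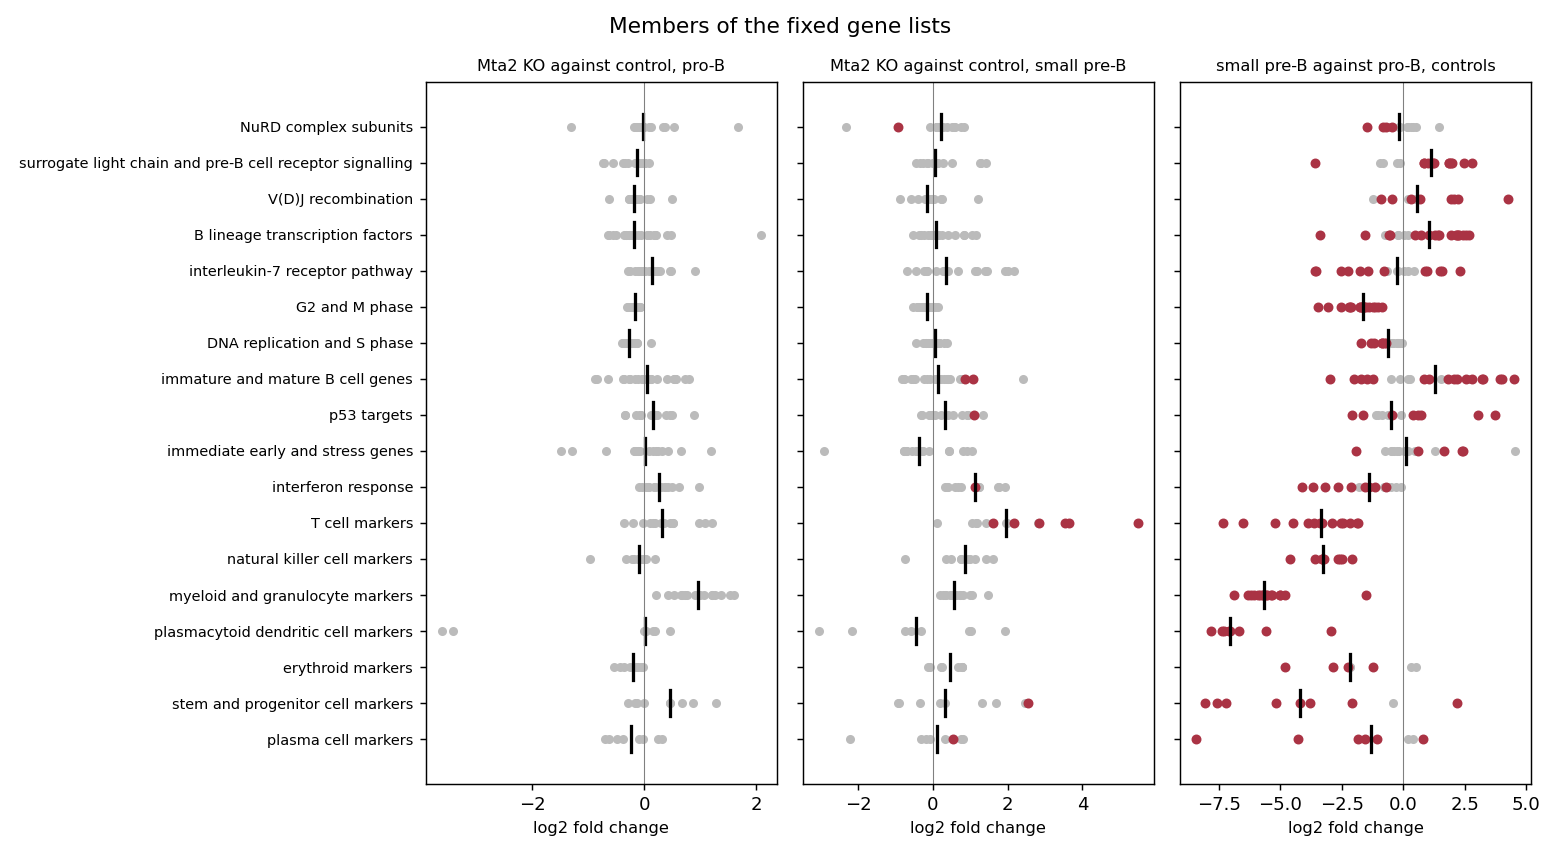
Log2 fold changes of the members of each gene list, other than the sex-linked one, for Mta2 KO against control in pro-B cells, in small pre-B cells, and for small pre-B against pro-B controls. Points are genes (red, adjusted p below 0.05), the black bar is the median of the list, and the T cell marker list has a median of 1.97 in small pre-B KO.

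Whether the effect of Mta2 loss differed between the stages was tested directly, as the KO effect in small pre-B minus that in pro-B cells. T cell markers had a larger log2 change in small pre-B than in pro-B cells as a list, by a median of 1.8. The camera adjusted p was 3.63e-06 with the preset correlation and 0.565 with an estimated one. Of its 14 members 0 passed over all genes and 5 adjusted over the list alone. Among them was Cd3e at 4.41, which was at 8.24 ± 0.869 and 17.4 ± 3.58 CPM in pro-B control and KO cells. In small pre-B cells Cd3e was at 0.0284 to 0.446 CPM in the controls and at 5.41 to 16.6 CPM in the KO libraries. All 14 markers were lower in small pre-B than in pro-B controls, by a median of -3.35. A larger log2 change from this lower start need not be a larger gain in CPM. The interferon response list differed by a median of 0.77 (camera adjusted p = 0.0014, Irf7 at 0.95) and natural killer markers by 0.97 (camera adjusted p = 0.0323, Tbx21 at 1.84). B lineage transcription factors differed by 0.21 (camera adjusted p = 0.0447, Pou2af1 at 0.90 and Pax5 at 0.70). These 3 lists had 0 members passing, over all genes or adjusted over the list alone. None of the 4 calls held with an estimated correlation (adjusted p = 0.721 for natural killer markers and 0.565 for the other lists with an estimated correlation). Pou2af1, which encodes the coactivator OCA-B, was at 506 ± 91.9 and 356 ± 86.6 CPM in pro-B control and KO cells (SD, n = 2) and at 2240 ± 248 and 2950 ± 435 CPM in small pre-B control and KO cells (SD, n = 3). The other lists had camera adjusted p from 0.0502 to 0.997. The sign of the median or mean and that of the test differed for the immediate early and stem cell lists.

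No single gene passed the test of the difference (0 by edgeR quasi-likelihood and 0 by limma-voom, 56 by DESeq2, 907 at an unadjusted p below 0.05), so a call in 1 cell type and not the other does not show that a gene's response differed. The smallest p belonged, in the direction of a higher effect in small pre-B cells, to Tenm4 (3.87), Tmem119 (3.70), Notch3 (2.42), Cltb (1.30) and Rras2 (0.91). In the other direction it belonged to Slc46a3 (-1.55), Klc3 (-1.63), the proton-sensing receptor gene Gpr4 (-4.37), Zmpste24 (-1.10) and Olfml2b (-1.23), with adjusted p of 0.43 to 0.471 in both directions. Gpr4 was at 6.41 ± 0.495 and 65.9 ± 2.43 CPM in pro-B control and KO cells and at 1.25 ± 1.04 and 0.641 ± 0.116 CPM in small pre-B cells. Mta2 differed by 0.38 (adjusted p = 0.809). Without small pre-B control 2 the count was 40, and it was 1 without small pre-B control 3 or without small pre-B KO 3. The interferon call was lost without pro-B control 2 (adjusted p = 0.0627) or pro-B KO 2 (0.11), the natural killer call without pro-B KO 2 (0.11), small pre-B control 3 (0.198) or small pre-B KO 2 (0.121), and the transcription factor call without pro-B control 1 (0.117), pro-B KO 2 (0.11), small pre-B control 1 (0.0698), control 3 (0.0518), KO 2 (0.0775) or KO 3 (0.106).

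Control small pre-B cells were set against control pro-B cells to give the stage difference beside which the KO effects can be placed. Rag1 rose from 221 ± 8.51 CPM (SD, n = 2) to 4260 ± 1480 CPM (SD, n = 3) and Rag2 from 64.4 ± 7.48 to 247 ± 32.4 CPM. Pax5 rose from 99.9 ± 14.6 to 480 ± 14.1 CPM, Ikzf3 from 150 ± 16.3 to 801 ± 109 CPM and Il7r from 324 ± 49.3 to 960 ± 121 CPM. Myc fell from 83.0 ± 13.5 to 7.18 ± 4.45 CPM. Igll1 (229 ± 12.3 and 129 ± 68.4 CPM, adjusted p = 0.147) and Vpreb1 (85.0 ± 7.11 and 72.1 ± 48.6 CPM, adjusted p = 0.735) did not pass, and Mta2 had a log2 difference of -0.15 (adjusted p = 0.566).

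By list, 11 of 16 surrogate light chain and pre-B cell receptor genes rose and 1 fell (median 1.12, camera adjusted p = 0.00537), with Cd79b at 2.79 and Blk at 1.95. Of 13 V(D)J recombination genes 6 rose and 2 fell (median 0.54, camera adjusted p = 0.0356), with Xrcc6 at 2.21 and Lig4 at 2.07, both of DNA end joining. Of 23 B lineage transcription factors 14 rose and 4 fell (median 1.05, camera adjusted p = 0.0042), with Bach2 at 2.66, Foxo1 at 1.95 and Irf8 at -3.38. Of 24 immature and mature B cell genes 12 rose and 5 fell (median 1.29, camera adjusted p = 0.0188), with Cd55 at 3.21 and Ccr7 at 2.18. Of 20 G2 and M phase genes 19 fell (median -1.66, camera adjusted p = 6.2e-05), with Ccnb1 at -2.16 and Aurka at -2.54. Of 20 S phase genes 7 fell (median -0.63, camera adjusted p = 0.0484), with Tk1 at -1.33 and Tyms at -1.73. Counts adjusted over the list alone were the same for these lists except 5 lower S phase genes and 6 lower mature B cell genes. With an estimated correlation none of these 6 calls held (adjusted p = 0.287 to 0.79 with an estimated correlation).

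Markers of other blood cells were lower in small pre-B than in pro-B controls. All 16 myeloid markers fell (median -5.66, camera adjusted p = 1.01e-06). The growth factor receptor gene Csf3r went from 183 ± 1.59 to 1.60 ± 0.612 CPM, and the transcription factor gene Cebpa was at -6.33. All 8 plasmacytoid dendritic cell markers fell (median -7.06, camera adjusted p = 0.000322). Runx2 went from 1020 ± 1.41 to 6.58 ± 4.15 CPM and Bst2 from 448 ± 51.4 to 9.30 ± 3.22 CPM. All 14 T cell markers (median -3.35, camera adjusted p = 0.00021, Cd247 at -2.54) and all 10 natural killer markers (median -3.25, camera adjusted p = 0.0101) fell too. So did 9 of 15 interferon response genes (median -1.39, camera adjusted p = 0.00654, Irf7 at -4.11) and 7 of 9 stem and progenitor markers (median -4.22, or -4.14 with members at 0 counts set at their bound, camera adjusted p = 0.0101). Flt3 went from 273 ± 41.2 to 1.89 ± 0.559 CPM, while 1 stem and progenitor marker rose. Adjusted over the list alone the counts were the same except 10 lower interferon response genes. These 6 calls were also lost with an estimated correlation (adjusted p = 0.287 to 0.611 with an estimated correlation). Not called were the erythroid markers (4 of 8 lower, median -2.17, camera adjusted p = 0.109), plasma cell markers (1 higher and 5 lower of 8, median -1.32, camera adjusted p = 0.127, Xbp1 at -1.83) and interleukin-7 receptor pathway (5 higher and 7 lower of 18, median -0.25, camera adjusted p = 0.638). The p53 targets (5 higher and 3 lower of 14, median -0.48 but mean 0.01 and an upward test, camera adjusted p = 0.927), immediate early genes (4 higher and 1 lower of 16, median 0.11, camera adjusted p = 0.59) and sex-linked genes (0 of 5, median 1.38, camera adjusted p = 0.59) were not called either. The same held for the NuRD subunits (4 lower of 15, or 3 adjusted over the list alone, median -0.17, camera adjusted p = 0.607, Mta1 at -1.48). For these lists, other than NuRD, the counts adjusted over the list alone were the same.

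In all, 7847 genes passed the edgeR quasi-likelihood test between the stages, 3687 higher and 4160 lower in small pre-B controls. Of these 4683 had an absolute log2 fold change of at least 1. The largest decreases included Clec4a3, at least 132-fold lower, and the chemokine receptor gene Ccr10, at least 124-fold lower, each with 0 counts in small pre-B controls. Ptafr, B3galnt1 and Ceacam10 had ratios of 0.0019 (counting interval 0.000391 to 0.00556), 0.00205 (0.000248 to 0.00743) and 0.00184 (4.64e-05 to 0.0103). Cd34, a progenitor surface protein, had a ratio of 0.00322 (0.000389 to 0.0117). Of the 5 genes that rose most, Gucy2g was at least 20.3-fold higher, and the other 4 were histone genes, Hist1h1e, Hist2h4, Hist1h1d and Hist1h3d. Gucy2g was at 0.0557, 1.69 and 0.0284 CPM in small pre-B controls 1 to 3, so its rise rests on control 2, and its call was lost without that library. Hist1h1e was at 1260 CPM in small pre-B control 3 and at most 6.75 CPM in any other library. The choice to count histone genes was made after their values were seen. Of these 28 of 51 rose between the stages, and 11 of 44 without small pre-B control 3.

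Of the 40 stage genes named that passed, 35 kept the call in every alternative and the exceptions were Gucy2g and the 4 histone genes. The V(D)J list was not called without small pre-B control 3 (adjusted p = 0.0813), and the S phase list was not called without pro-B control 1 (0.164), small pre-B control 1 (0.132), control 3 (0.103) or small pre-B KO 2 (0.0556).

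The KO effects of both cell types pointed the same way for most genes changed in small pre-B cells. Of the 267 genes that rose in small pre-B KO, 253 had a positive log2 fold change in pro-B KO (median 0.54, against 1.63 in small pre-B), and of the 161 that fell, 135 had a negative one (median -0.25, against -1.04). Across the 14161 genes tested, which are not independent replicates, Pearson's r was 0.329 and Spearman's rho 0.353, and r was 0.76 over the 428 genes called in small pre-B cells. Of the 5 genes called in pro-B cells 2, Sva and Tjp1, were also called higher in small pre-B cells, against 0.0943 by chance (Fisher's exact test, two-sided, p = 0.00341), and 0 were shared in the lower direction.

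Genes that fell from pro-B to small pre-B controls tended to be higher in small pre-B KO cells. Those that rose tended to be lower in KO. The genes that fell include markers of other blood cells, so this difference need not be one of B cell stage alone. Kit, Irf7, Xbp1 and the T cell receptor gene Cd247 rose in KO and fell with stage. Of the 267 genes higher in KO, 166 fell with stage and 29 rose. Of the 161 lower in KO, 68 rose with stage and 36 fell. The shared small pre-B controls add to such counts, so the controls were also divided into separate sets for the KO effect and the stage difference. With controls 1 and 2 for KO and control 3 for the stages, 171 genes were higher in KO, of which 127 fell with stage, against 54.4 by the stage share of all genes, and 16 rose, against 48.9. Of 109 lower genes 55 rose, against 31.2, and 22 fell, against 34.7. With controls 1 and 3 for KO, 360 of 950 higher genes fell, against 175, 161 rose, against 160, and 178 of 724 lower genes rose, against 122, while 108 fell, against 133. With control 3 for KO, 1156 of 2495 higher genes fell, against 755, 469 rose, against 681, and 1142 of 2345 lower genes rose, against 640, while 328 fell, against 710. The other 3 divisions called at most 13 genes. Over all tested genes r was -0.443 and the covariance -0.88. Both contrasts use the small pre-B controls, which gives a negative relation by itself, with a mean r of -0.0996 (lowest -0.13) and a mean covariance of -0.103 (lowest -0.133) in 20 simulations without a KO effect. The simulations do not copy the larger spread of control 3, and over the 6 divisions of the controls r was -0.316 to -0.232. Without small pre-B control 2 r was -0.56, and without small pre-B KO 2 it was -0.311. The effect of KO in pro-B cells, which shares the pro-B controls with the stage difference, had an r of -0.149 with it, and of -0.268 over genes with a mean of at least 10 CPM. These shared controls enter both with the same sign and push that r upward, and no value without a KO effect was computed for it.

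**Figure D3:**
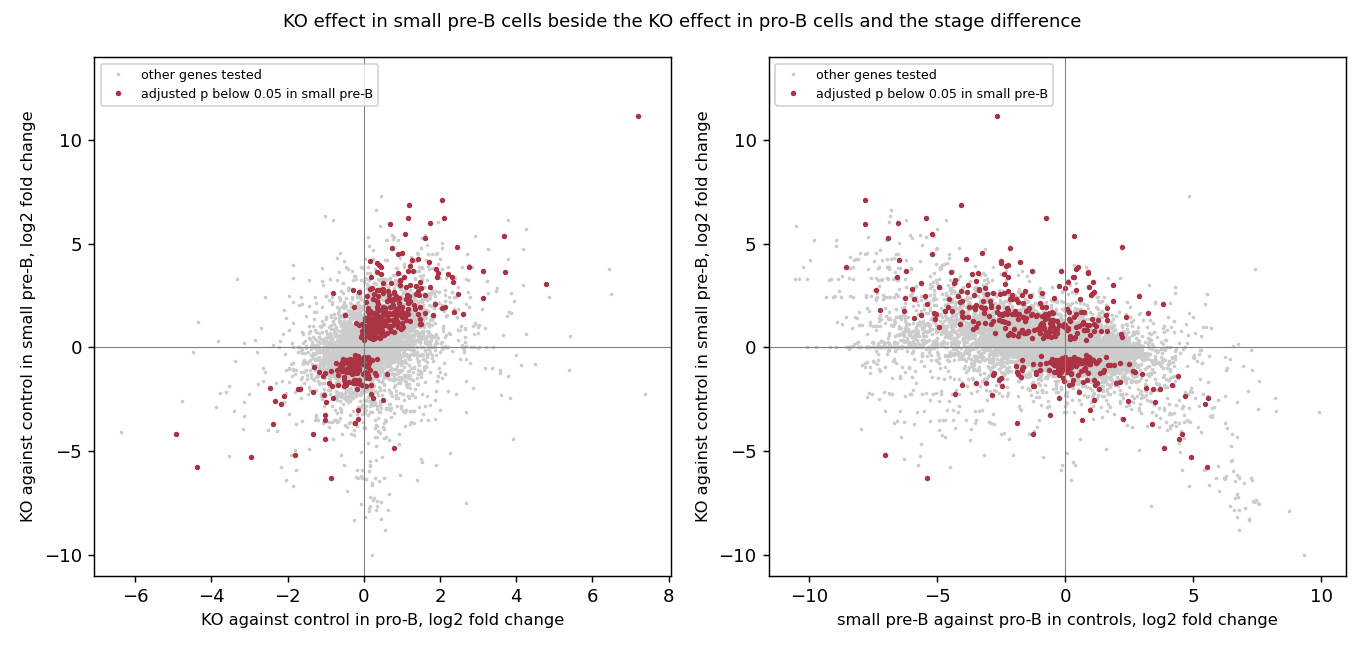
Log2 fold change of Mta2 KO against control in small pre-B cells, plotted against the KO effect in pro-B cells and against the stage difference in controls. Each point is 1 of 14161 genes, with the genes called in small pre-B KO in colour, and r is 0.329 in the first panel and -0.443 in the second.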

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

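The tests of T cells, of natural killer cells and of the sex of the animals in this part were chosen only after the levels of these genes had been seen.

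The KO effect on the log2 scale differed between small pre-B and pro-B cells by the test of the difference for 4 gene lists. The median difference in log2 fold change was 1.8 for T cell markers, 0.772 for interferon response genes, 0.966 for natural killer markers and 0.206 for B lineage transcription factors, and with an estimated correlation none of the 4 lists was called (adjusted p = 0.565 to 0.721 with an estimated correlation).

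The T cell markers were weighed further, because Cd3e lay 12.1 to 37.1 times above the highest small pre-B control in the KO libraries. CD4 or CD8 T cells in the sorted fraction are argued against in KO libraries 1 and 3, since in both (2 of 2 libraries) the summed Cd4 and Cd8a did not exceed the highest control, whereas in KO library 2 it reached 9.96 CPM against at most 3.46 CPM in a control, so such cells may contribute there. The summed natural killer markers were at 114 and 110 CPM in KO libraries 1 and 3. In control 2 they were at 147 CPM, where Cd3e was at 0.282 CPM. This argues against natural killer cells as the source in KO libraries 1 and 3. In KO library 2 the sum reached 210 CPM, 1.43 times the highest control. That factor cannot decide, since Cd3e started at no more than 0.446 CPM in controls, so natural killer cells stay open there. The abundant T cell genes Lck and Tcf7 were at 59.4 to 87.3 and 28.7 to 50.3 CPM in KO and at 12.7 to 51 and 1.79 to 18.1 CPM in controls, while the sex of the animals is argued against in KO library 3, which had Y-linked RNA like the controls and where Cd3e, Cd3d and Cd247, the chains also called without that library, lay at 2.03 times the highest control or more. An effect of Mta2 loss on these genes in B lineage cells stays open, as do sex in KO libraries 1 and 2, which had almost no Y-linked RNA, and T cells without Cd4 and Cd8a, although the gate for B220 and against CD43 would remove most T cells.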

How the results depend on the processing

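The alternatives with Y-linked RNA, without Rn45s, with the GC trend removed, with the header number as block and with the small pre-B libraries without control 3 were chosen only after the data were seen. The libraries with Y-linked RNA hold small pre-B KO 3 as the only small pre-B KO library. With Y-linked RNA as a covariate the small pre-B KO effect also rests on that library. A lower count there may come from fewer libraries, so it cannot decide on sex. Among the named genes no called value reversed its direction by more than its SE. The other called genes were not checked for this. The 5 genes called in pro-B KO became 181 with DESeq2, 148 with limma-voom, 8 with no filter, 8 with the 1 CPM filter, 856 when only the compared groups were fitted, and 0 with the title number as replicate block, with the header number as replicate block and in the libraries with Y-linked RNA. Leaving out each library gave 0 to 25, with 0 without pro-B control 1, pro-B control 2 or pro-B KO 2, 14 without small pre-B control 2 and 25 without small pre-B control 3. The 428 genes in small pre-B KO became 1821 with DESeq2, 0 when only the compared groups were fitted, 153 with the title number as replicate block, 115 of them shared with the 428, 0 with the header number as replicate block, 0 in the libraries with Y-linked RNA, 1 with Y-linked RNA as a covariate and 5 with the small pre-B libraries without control 3. Leaving out each library gave 1 (without control 1) to 1667 (without control 2), with 280 without control 3, 4, 18 and 149 without KO 1, 2 and 3, 10 without either pro-B control and 15 and 14 without pro-B KO 1 and 2. The 0 genes with a different KO effect became 56 with DESeq2 and 0 to 40 on leaving out each library, 40 without small pre-B control 2 and 1 without small pre-B control 3 or KO 3. The 7847 stage genes became 4683 with an absolute log2 fold change of at least 1, by construction, and 5335 to 8086 on leaving out each library. Lists called fell to 0 in each comparison with camera and an estimated correlation. On leaving out each library they went from 3 to 1 to 6 in pro-B KO (1 without pro-B control 1 or small pre-B control 2 or 3, 6 without pro-B control 2 or KO 1), from 2 to 2 to 5 in small pre-B KO (5 without control 1 or KO 3, 4 without control 2), from 4 to 1 to 7 for the difference (1 without pro-B KO 2, 2 without small pre-B control 3, 7 without small pre-B KO 1 or 3) and from 12 to 10 to 13 for the stages. With the title number as replicate block camera called 5 lists in small pre-B KO. The correlation of the KO effects was 0.231 to 0.412 on leaving out each library, and that with the stage difference -0.56 (without small pre-B control 2) to -0.311 (without small pre-B KO 2). Of the values of named genes under alternatives 3224 stayed on their side of the threshold, 468 lost the call and 101 gained one. A change of sign was not counted as a reversal where a value without a call lay within its SE. The title numbers were not read as pairing in the main fit, since the labels do not say what they stand for. After removal of the group means, control and KO libraries sharing a number correlated at 0.0843 to 0.263. Control and KO libraries with different numbers lay lower, at -0.157 to 0.0262. Deviations from a group mean cancel out, so higher values for shared numbers push the others down. In pro-B cells, with 2 libraries per group, the values are mirror images, at 0.102 and -0.102. The gap between the ranges is thus partly fixed in advance. A preparation shared by title number therefore stays open, and the main fit does not allow for it. The cause of the shifts between alternatives was not tested separately. Fewer libraries leave fewer degrees of freedom, which alone would not raise the count, as from 5 to 856 in pro-B cells. The main fit shares its spread estimate for a gene over all groups. Chi-square per degree of freedom was 22.6 and 31.4 between pro-B replicates. It was 214.5 and 225 between small pre-B control 3 and the other small pre-B controls. The fits of the compared groups alone drop this sharing and gave 856 genes in pro-B and 0 in small pre-B cells. The pro-B count of 5 was thus lower with the shared spread. In small pre-B cells fewer degrees of freedom could lower the count too, so that fit cannot tell whether sharing raised it. Alternatives for transcripts were not run, since genes were deposited, the block could not be fitted for the stages, and the compared groups alone are all groups for the difference. A level of 3 counts is 0.054 CPM in the deepest library and 0.173 CPM in the shallowest.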

Other observations

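The tests of small pre-B control 3 on the called genes, of the sex of the animals, of plasmacytoid dendritic cells and of dividing cells were chosen only after the results were seen, as were the genes beside Cd3e and the count of genes by chromosome.

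Cd3g, Cd3d, Cd3e, Mpzl2 and Amica1, which rose in small pre-B KO by 3.64, 2.83, 5.49, 4.86 and 2.09 on the log2 scale, lie within a single stretch of chromosome 9, from 44969572, the start of Cd3g, to 45108531, the end of Amica1. Of the measured genes in that stretch Mpzl3 was the exception, at -0.30 (adjusted p = 0.55, edgeR quasi-likelihood), and the genes that flank it, Ube4a and Scn2b, were at 0.08 and 0.14 (adjusted p = 0.781 and 0.744). In pro-B KO the same 5 genes were at 0.35, 0.51, 1.08, 2.45 and 0.38, and none of them passed there.

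Chromosome 7 held 39 of the genes with an unadjusted p below 0.01 in pro-B KO, against 23.2 by its share of genes (odds ratio 1.81, Fisher's exact test, two-sided, adjusted p = 0.0276 over 20 chromosomes). In small pre-B KO it held 100 against 108 (adjusted p = 1). Tjp1 and Klc3 lie on chromosome 7. A chromosome segment around Mta2 that differs between KO and control animals would be a candidate source of changes near the gene; genes within 10 Mb of Mta2 had an odds ratio of 1.27 (interval 0.503 to 2.7, Fisher's exact test p = 0.511) for an unadjusted p below 0.01 in pro-B cells, an interval too wide to decide. In small pre-B cells 26 of these 262 genes had such a p (odds ratio 1, interval 0.64 to 1.51, Fisher's exact test p = 1), so no excess was seen there.

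The 428 genes called in small pre-B KO were weighed against 4 explanations. Chance could not be tested to below 0.05, since the 6 libraries make 10 splits into 3 and 3; the real split gave 428 genes, 1 split in all gave as many, and the highest of the others gave 8. After removal of the GC trend the called genes kept a median of 0.976 of their log2 fold change (0.964 to 0.985). This argues against GC content as the whole cause. Without small pre-B control 3 they kept 0.883 (0.736 to 1.06 when another library was left out with it). That value cannot decide on control 3, since the genes were chosen with that library in the fit. In all 428 the KO libraries already lay beyond each control. A fit of all groups without control 3 called 280 genes, 224 of them among the 428, and the small pre-B libraries alone without it gave 5. The sex of the animals stays open as a part of the cause, since sex and genotype cannot be told apart in KO libraries 1 and 2. KO library 3 had Y-linked RNA like the controls. Over the 149 genes called without it, that library had a median of 0.717 of their effect (0.528 to 0.88 over 3 divisions of the controls). All pro-B libraries had Y-linked RNA, at 224 to 273 CPM, and there 388 of the 428 genes changed in the same direction. This argues against sex as the whole source of the directions, though genes are not independent replicates and pro-B groups had 2 libraries each. Sex may account for a part of the changes, and an effect of Mta2 loss stays open beside it.

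The lower expression in small pre-B KO of genes that rise from the pro-B stage, and the higher expression of those that fall, were weighed in the same way. Shared control libraries are argued against as the whole cause, since the covariance stayed negative in each of 6 divisions of the controls into separate sets, from -0.524 to -0.19, and so is control 3, since it was -0.14 and -0.133 with controls 1 and 2 alone. Plasmacytoid dendritic cells of the pro-B gate are argued against by their abundant genes Siglech, Ccr9 and Runx2, which reached at most 1.4% of the pro-B level in a small pre-B KO library, where the 166 genes would need a median of 47.3% and a lower quartile of 22.5%; of the other members of the list Cox6a2 reached 33.6% to 77.9%, and the rest at most 4.52%. More dividing cells are argued against by the G2 and M phase list, whose median was -0.154 (-0.264 to -0.00428), against a lower quartile of 1.17 for the 166 genes. An earlier developmental state of the KO cells may give such a pattern and was not tested. The 4 lists called higher with stage were not called lower in small pre-B KO. Their medians there were 0.07 (surrogate light chain and pre-B cell receptor), -0.15 (V(D)J recombination), 0.08 (B lineage transcription factors) and 0.13 (immature and mature B cells). The sex of the animals and other cells of the pro-B gate stay open.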
